A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

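Total RNA of 6 cultures of Saccharomyces cerevisiae strain BY4742 was measured on Affymetrix GeneChips, 3 cultures with clioquinol (CQ) and 3 with the solvent dimethyl sulfoxide (DMSO). Per the labels' protocols, cells in mid-log phase in the rich medium YPD were diluted into fresh YPD that held either 80 µM CQ or 1% DMSO, RNA was extracted with hot phenol after 5 h, and biotin-labelled cRNA was made by the manufacturer's procedure. The labels call the 3 samples of each group biological replicates, and give no culture days or hybridisation batches. They give no DMSO content for the CQ cultures, so an effect of DMSO itself cannot be separated from that of CQ.

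The values used were the authors' deposited table of 1 linear intensity per probe set and array. The values were never negative and had similar distributions on the 6 arrays, with medians over the genes from 889.7 to 1008. The software for scanning and summarising, and whether the arrays were scaled to one another, are not given in the sources used here. The overall level of each array was not tied to a number of cells, so a change in total mRNA per cell cannot be seen, and every difference is relative to the other transcripts of the array. The highest values lay close together near the top of the scale, so that differences of the brightest transcripts can be understated.

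The table held 10928 probe sets. The annotation table paired 5498 of them with 1 S. cerevisiae gene and 1746 with genes of the fission yeast Schizosaccharomyces pombe, which the array also carries; 1 probe set was paired with several genes and left out, and 3683 were without a gene there, 166 of them control probe sets. Gene symbols were matched by identifier to a table of 6477 S. cerevisiae genes, which updated 12 symbols. For each of the 47 genes with several probe sets the probe set with the highest mean over the 6 arrays was used, which left 5449 genes. Probe sets that the manufacturer marks as shared by related sequences measured 119 of these genes, and values of those genes can include a near-identical copy. No chromosome coordinates are given, because no genome build is named for the array annotation.

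All comparisons used log2(intensity + 16). A pseudocount understates the change of dim genes. The background level was the 95th percentile of the fission yeast probe sets, an intensity of 43.7 over the 6 arrays. Where every array of a group lay at or under its own background level, the difference is given as a bound: the mean of the brighter group against the mean of the dimmer group, with each array of the dimmer group raised to its background level. Differences between CQ and DMSO were fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the 5449 genes and a threshold of 0.05 on the adjusted p. A gene that passed is described as having risen or fallen, and the values after ± are standard errors of the moderated fit for log2 differences and standard deviations over 3 arrays for intensities. The precision is limited by the number of arrays. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

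The design, the tests, 41 gene lists, the rule for named genes and 16 alternatives were fixed before the data were examined. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 41 lists, and a list past the threshold is described as called. Camera asks whether a list moved differently from the other genes of the array. Each list was tested again with the correlation estimated from the arrays, with camera on ranks, and with fry, whose p tests whether the genes of a list move on balance in 1 direction. With an estimated correlation camera takes its p from the 4 residual degrees of freedom of the fit, which it does not at the preset correlation. Counts of members are given after adjustment over all genes and adjusted over the list alone. Of the listed genes, 14 were not measured under a name of their own.

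Candidates passed the threshold, had no overlap between arrays of the groups and lay above background in the brighter group. Of these, the 12 with the largest increase and the 12 with the largest decrease were named. The 4 members of each called list with the largest change were added, and the 2 members with the largest difference in each list that was not called. Named whatever their values were 9 genes of metal uptake, storage and regulation and the 4 marker genes deleted in BY4742. Members named as exceptions to the direction of their list fall outside this rule and were chosen after their values were seen.

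The alternatives were quantile normalization, centring on the median or on the 75th percentile, leaving out genes under background or the dimmest 40%, other summaries of probe sets, an intensity trend or robust variances in eBayes, the replicate number as a block, leaving out each array in turn, pseudocounts of 1 and 64, and the other list tests. After the data were seen, 2 more were added: a fit with the 3' to 5' index of each array as a covariate, and a fit after removal of each array's trend on coding length. The index is the mean, over 6 yeast control genes with separate probe sets near both ends of the transcript (ACT1, RIP1, WBP1, SPT15, SRB4 and EAF5), of the log2 difference between the 3' and the 5' probe set. The same index was taken over 4 bacterial spike-in RNAs (dap, lys, phe and thr). The yeast control gene TDH1 also has 3' and 5' probe sets and is not in the index.

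The scripts were tested on simulated data for this comparison, with the real array count and 5449 genes. Each gene had 1 spread, pooled over both groups, although the real spread was larger with CQ. Of the genes changed by a log2 difference of 0.5, 58.2% were recovered, and at 1 the share was 88.1% and at 2 it was 100%. Only 67, 67 and 66 genes were changed at these sizes, besides 28 in a shifted list. In the real data 68.0% of the genes passed, so these shares cannot be carried over to the real comparison. Unchanged genes made up 5.91% of the calls, and 0 unshifted lists were called by camera. Simulated genes varied independently, so this test says nothing about lists whose members vary together from array to array.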

Results

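The experiment measured transcript levels in the haploid laboratory strain BY4742, a descendant of S288C with mating type alpha. Cultures were held for 5 h with 80 µM clioquinol (CQ) or with 1% of the solvent DMSO. CQ is a halogenated hydroxyquinoline that binds copper, zinc and iron ions. Each group held 3 biological replicates, 1 array each, and a single comparison follows from the design: how expression differed between CQ and DMSO cultures. Median intensities over the 5449 genes were 926.1, 891.4 and 889.7 on the DMSO arrays and 993.6, 976.9 and 1008 on the CQ arrays, and 97.8 to 98.7% of the genes lay above background on each array.

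Arrays of the same group resembled one another more than arrays of different groups. Pearson correlations across genes were 0.9951 to 0.9968 among DMSO arrays, 0.9799 to 0.9928 among CQ arrays and 0.8625 to 0.8878 between groups. The median standard deviation of a gene was 0.07 on the log2 scale with DMSO and 0.13 with CQ. The leading principal component held 90.7% of the variance and separated the groups, and the next held 5.48%, with CQ replicate 2 at -14.49 and the other arrays between -0.75 and 9.12. The hybridisation control bioB was also brighter on CQ replicate 2, at 1190, than on the other 5 arrays, where it lay between 246 and 549.

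The 3' to 5' index, a sign of RNA integrity and labelling, was higher on every CQ array. Its mean was 0.93 with DMSO (0.96, 0.96 and 0.88) and 1.33 with CQ (1.30, 1.53 and 1.15), a difference of 0.40 on the log2 scale. An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 arrays allow. By gene the difference ran from 0.13 for ACT1 to 0.98 for SRB4, and the groups overlapped for EAF5 (0.14). TDH1, which is not in the index, differed by 0.05 on its 3' and on its 5' probe set. Its mean intensities of 11600 to 13080 lay near the top of the scale, where differences can be understated. The spike-in RNAs differed by 0.19 (exact permutation p = 0.2), with CQ replicate 2 at 1.33, the other CQ arrays at 0.89 and 0.90 and the DMSO arrays between 0.81 and 0.90.

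**Figure D1:**
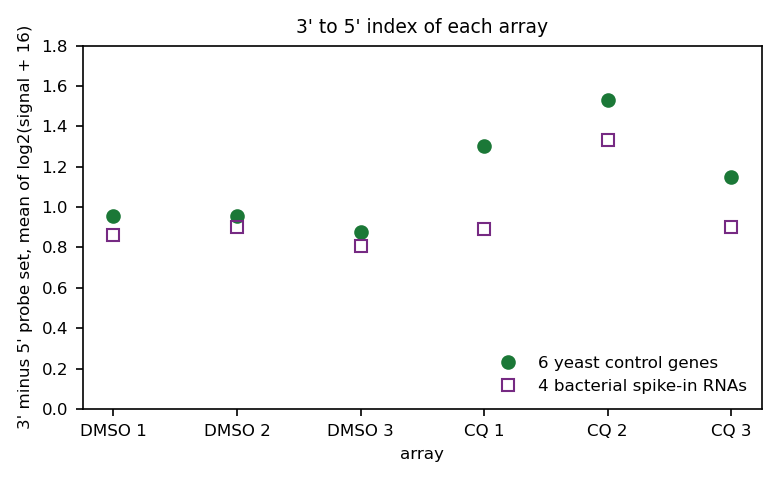
The 3' to 5' index of the 6 arrays, as the mean log2 difference between 3' and 5' probe sets with a pseudocount of 16, for 6 yeast control genes (filled circles) and 4 bacterial spike-in RNAs (open squares). The yeast index lay at 0.88 to 0.96 on the DMSO arrays and at 1.15 to 1.53 on the CQ arrays, and the spike-in index stood apart on CQ replicate 2, at 1.33.

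The strain carries deletions at 4 marker genes, which check the labels and the background. LEU2 (45.4 ± 11.6 with DMSO, 33.6 ± 7.96 with CQ), LYS2 (11.7 ± 1.74 and 9.82 ± 3.24) and URA3 (16.5 ± 1.97 and 18.6 ± 1.34) gave intensities near or below background in both groups (n = 3 each). HIS3 read 1598 ± 92.1 with DMSO and 881 ± 209 with CQ. The his3 allele of BY4742 lacks an internal part of the gene, and a probe set outside that part checks nothing.

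A large part of the transcriptome differed between the CQ and the DMSO cultures. Most genes of the iron, zinc and drug-resistance lists rose, and most genes of ribosome assembly, ribosomal proteins, respiration and iron-containing proteins fell. Camera called these lists at the preset correlation and none of them with an estimated correlation. Of 5449 genes, 1969 rose and 1739 fell (68.0% of the genes tested), and 529 rose and 409 fell at least 2-fold. Arrays of the groups did not overlap for 4017 genes, 73.7% of those tested, where chance gives 10%. With each array centred on its median the split became 1578 genes higher with CQ and 2211 genes lower with CQ; the median gene differed by 0.02 as deposited and by -0.11 after that centring, and changes of that size cannot be assigned a direction. Without CQ replicate 2 the counts were 2109 genes higher with CQ and 1847 genes lower with CQ.

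Camera called 21 of the 41 lists, 9 higher and 12 lower. Called lists are given below with their adjusted p at the preset correlation. With an estimated correlation 0 lists were called (5 lay under 0.05 before adjustment), against the same 21 by camera on ranks. By fry, which asks another question, 32 were called. These were the 21 and 11 others: hexose transport, chaperones, phospholipid synthesis, a-specific genes, DNA damage, coenzyme Q, early G1, late G1 and S phase, reference genes, the phosphate regulon and copper uptake.

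**Figure D2:**
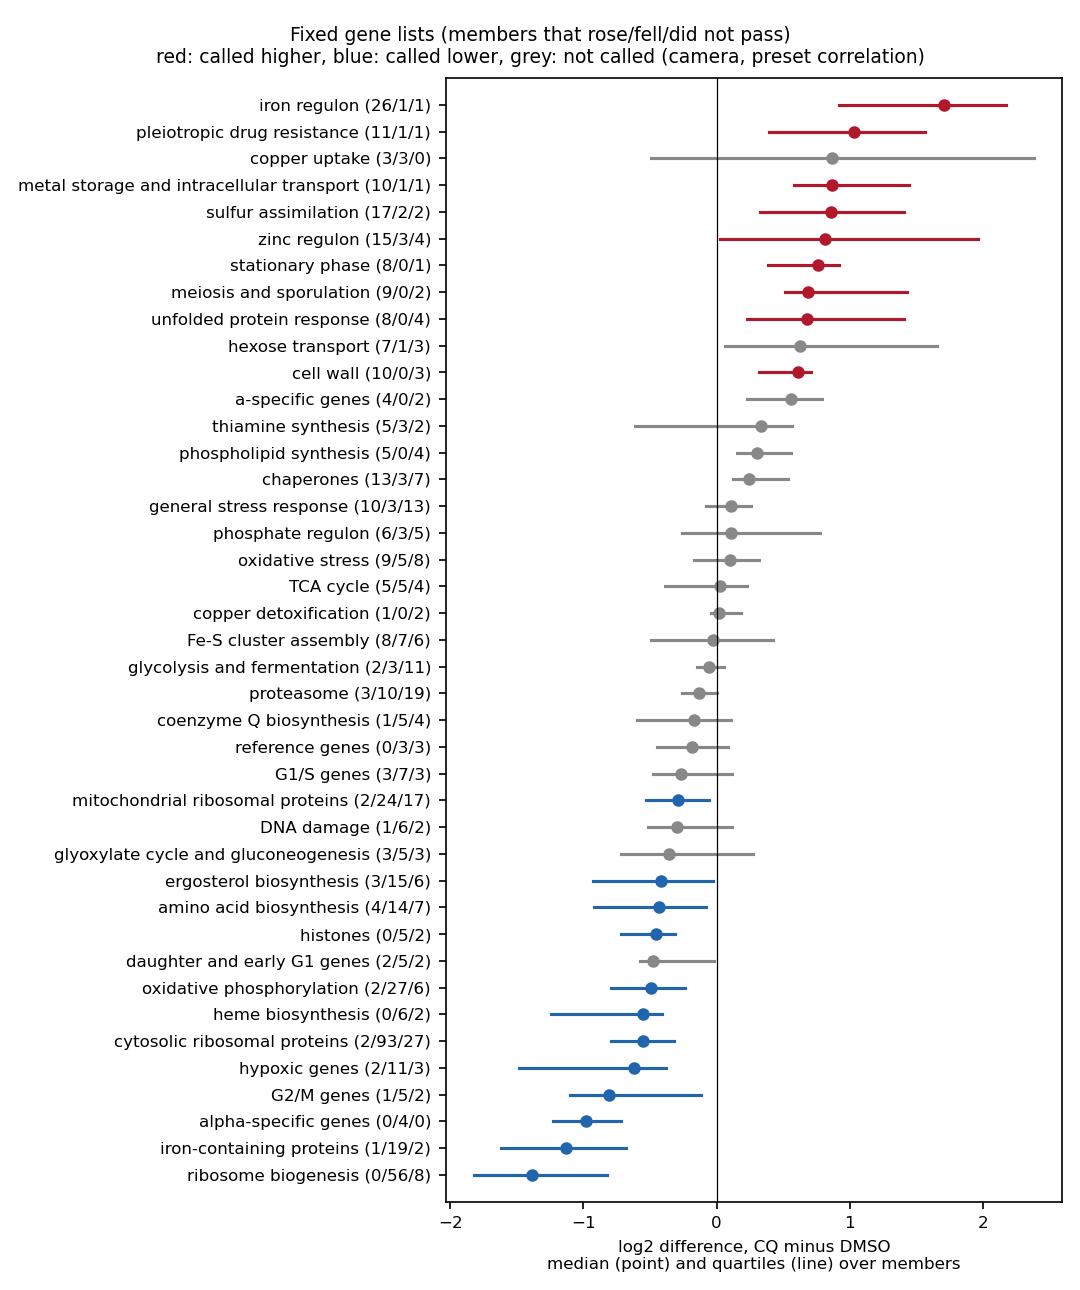
Median log2 difference between CQ and DMSO (points) and quartiles over the measured members (lines) of the 41 fixed gene lists, with the numbers of members that rose, fell or did not pass limma's threshold in parentheses. The iron regulon, with a median of 1.71, and ribosome biogenesis, with a median of -1.39, lay at the ends of the range.

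The iron regulon, the targets of the low-iron activators Aft1 and Aft2, rose almost throughout. Of its 28 measured members 26 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone and a median log2 difference of 1.71. The largest increases were in LSO1 (YJR005C-A), TIS11 (YLR136C), which encodes an mRNA-binding protein that promotes decay of transcripts for iron-using proteins, and the siderophore transporters ARN2 (YHL047C) and SIT1 (YEL065W). LSO1 lay below background with DMSO and was at least 14.3-fold higher with CQ; TIS11 rose by 4.58 ± 0.08 on the log2 scale, ARN2 by 3.13 ± 0.09 and SIT1 by 2.77 ± 0.09. The high-affinity uptake pair FET3 (YMR058W) and FTR1 (YER145C) went from 1690 ± 98.9 to 7386 ± 470 (log2 difference 2.12 ± 0.08) and from 625 ± 68.8 to 2325 ± 459 (1.85 ± 0.15). FIT2 (YOR382W), a cell wall protein that retains siderophores, went from 2602 ± 231 to 11260 ± 479 (2.11 ± 0.09), and with CQ stood at 77.3% of the array maximum. The exceptions, named after their values were seen, were VHT1, a biotin transporter, which fell by 1.38, and MRS4, at 0.13. The camera adjusted p was 2.07e-09, and with an estimated correlation the adjusted p = 0.35.

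**Figure D3:**
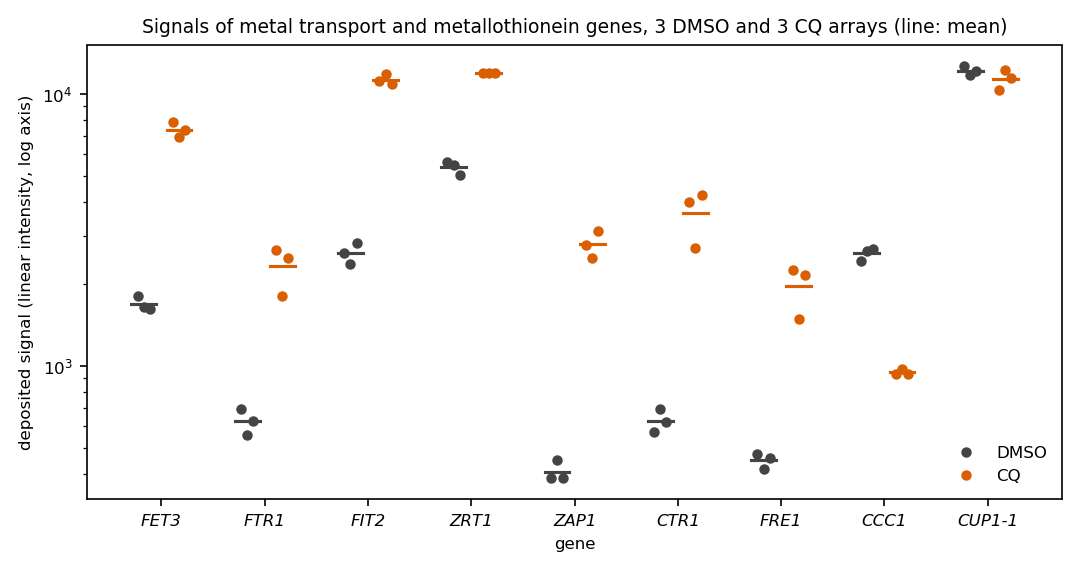
Deposited intensities (log axis) of 9 genes of metal uptake, storage and regulation on the 3 DMSO and 3 CQ arrays (points) with group means (lines). FET3, FTR1, FIT2, ZRT1, ZAP1, CTR1 and FRE1 were higher on all 3 CQ arrays, CCC1 was lower on all 3, and the groups overlapped for CUP1-1.

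Zinc-responsive genes rose in most cases. Of 22 measured targets of the low-zinc activator Zap1, 15 rose, 3 fell and 4 did not pass, with the same counts adjusted over the list alone and a median of 0.82. ZAP1 itself (YJL056C) went from 407 ± 38.2 to 2804 ± 318, a log2 difference of 2.73 ± 0.11. ZPS1 (YOL154W), a putative cell-surface protein, rose by 4.46 ± 0.11 to 84.0% of the array maximum, so that its increase can be understated, and YOR387C and VEL1 (YGL258W), of unknown function, were at least 19.0-fold and 8.65-fold higher, both being below background with DMSO. The high-affinity zinc transporter ZRT1 (YGL255W) went from 5363 ± 309 to 11880 ± 3.12, or 1.15 ± 0.07; at 81.5% of the array maximum with CQ its 3 arrays had almost the same value, so the same holds for it. The members that fell, named after their values were seen, were IZH1 (-2.11), IZH2 (-0.96) and the repressor gene NRG2 (-0.51). Camera gave an adjusted p of 0.00541, and the adjusted p was 0.485 with an estimated correlation.

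Copper genes split by member. Of the 6 targets of the low-copper activator Mac1, 3 rose and 3 fell, with a median of 0.87 and no call (camera adjusted p = 0.76). The transporter gene CTR1 (YPR124W) went from 627 ± 62.3 to 3657 ± 831, or 2.49 ± 0.17, and the metalloreductase genes FRE1 (YLR214W) and FRE7 (YOL152W) rose by 2.06 ± 0.16 and 3.56 ± 0.25. FRE1 also belongs to the iron list. CTR3 (-0.54), REE1 (-0.32) and IRC7 (-1.10), named after their values were seen, fell. Among the targets of the high-copper activator Ace1, the metallothionein gene CUP1-1 (YHR053C) read 12160 ± 446 with DMSO and 11350 ± 962 with CQ (log2 difference -0.10 ± 0.09, limma adjusted p = 0.319; -0.24 and 0.039 with arrays centred on their median). Its probe set is shared with its copy, and at 83.6 and 77.9% of the array maximum a small change can be hidden. In that list 1 of 3 members rose over all genes and 0 adjusted over the list alone (camera adjusted p = 0.882). The metallothionein gene CRS5 was the member that rose, by 0.35 ± 0.12, and its difference was 0.22 without CQ replicate 2. CRS5 did not pass without DMSO replicate 2 or 3 or with arrays centred on their 75th percentile or median (0.22 with the median), and it stood at -0.09 with the 3' to 5' index as a covariate.

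Vacuolar and secretory metal transporters were higher in 10 of 12 measured cases, with 1 lower and 1 not past the threshold, the same adjusted over the list alone, and a median of 0.87. ATX2, a manganese transporter, rose by 2.16 ± 0.15, the cadmium-exporting ATPase PCA1 by 1.68 ± 0.09 and the zinc transporter subunit ZRG17 by 1.67 ± 0.18. CCC1 (YLR220W), which carries iron into the vacuole, went the other way, from 2589 ± 143 to 946 ± 22.5 (-1.44 ± 0.08). The list was called (camera adjusted p = 0.00632, and adjusted p = 0.485 with an estimated correlation), and it shares 3 genes with the iron list and 2 with the zinc list.

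Genes for proteins with an iron centre fell. Of 22 measured genes 19 fell, 1 rose and 2 did not pass, the same adjusted over the list alone, with a median of -1.13. The largest decreases were in ILV3 (-2.85 ± 0.09), an Fe-S enzyme of branched-chain amino acid synthesis, ERG5 (-2.78 ± 0.26), a cytochrome P450 of sterol synthesis, CYC1 (-2.69 ± 0.17), cytochrome c, and CTT1 (-2.16 ± 0.11), cytosolic catalase. NTG2, a DNA repair enzyme, rose by 0.30 and was named after its value was seen. With quantile normalization or with arrays centred on their median 0 members rose. Camera gave an adjusted p of 1.25e-06, against an adjusted p of 0.35 with an estimated correlation. The list shares 4 genes with the respiratory list, 4 with the ergosterol list and 2 with the tricarboxylic acid cycle list, so their changes are not separate findings. Genes of Fe-S cluster assembly split into 8 higher, 7 lower and 6 not past the threshold (the same counts of calls adjusted over the list alone, camera adjusted p = 0.913, median -0.03, mean 0.04). ISU2 (1.48 ± 0.08), a scaffold protein, and SSQ1 (1.02 ± 0.07), a chaperone, had the largest differences there.

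Respiratory genes fell: 27 of 35 measured subunits of the respiratory complexes and ATP synthase were lower, 2 higher and 6 not past the threshold (28 lower and 2 higher adjusted over the list alone), with a median of -0.49. Besides CYC1, the Rieske protein gene RIP1 (-1.25 ± 0.13) and the cytochrome oxidase genes COX6 (-1.24 ± 0.08) and COX5A (-1.04 ± 0.08) fell; ATP4 (0.22) and NDE1 (0.51), named after their values were seen, rose. The adjusted p was 3.89e-06 by camera and 0.485 with an estimated correlation. Heme biosynthesis followed, with 6 of 8 genes lower and 2 not past the threshold, the same adjusted over the list alone, and a median of -0.55 (-0.84 with the 3' to 5' index as a covariate). HEM13 (-2.71 ± 0.10), HEM3 (-1.25 ± 0.11), the ferrochelatase gene HEM15 (-1.24 ± 0.07) and HEM4 (-0.56 ± 0.11) fell most (camera adjusted p = 0.00632, and adjusted p = 0.35 with an estimated correlation). Tricarboxylic acid cycle genes split evenly, 5 higher, 5 lower and 4 not past the threshold, with SDH1 at -0.97 ± 0.09 and SDH3 at -0.90 ± 0.09; their median was 0.02, their mean -0.12, and camera made no call (adjusted p = 0.667). Coenzyme Q genes were lower in 5 of 10 cases and higher in 1 (camera adjusted p = 0.246), with CAT5 at -1.29 ± 0.07 and COQ2 at -0.87 ± 0.11.

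Sterol and hypoxic genes were lower. Of 24 ergosterol genes 15 fell, 3 rose and 6 did not pass, the same adjusted over the list alone, with a median of -0.41. After ERG5, the mevalonate and squalene enzymes MVD1 (-1.68 ± 0.11), IDI1 (-1.63 ± 0.07) and ERG1 (-1.54 ± 0.09) fell most, and NCP1, ERG8 and ERG27, named after their values were seen, rose by 0.32, 0.40 and 0.79. The call (camera adjusted p = 0.00632, and adjusted p = 0.616 with an estimated correlation) was lost with the 3' to 5' index, 0.40 higher with CQ, as a covariate (median -0.14, adjusted p = 0.154). Of 16 genes of growth without oxygen or heme, 11 fell, 2 rose and 3 did not pass, the same adjusted over the list alone, with a median of -0.62. The cell wall mannoprotein genes DAN1 (-2.97 ± 0.18) and TIR3 (-2.25 ± 0.17) and the translation factor gene ANB1 (-2.54 ± 0.22) fell, while AUS1 (1.68), a sterol importer, and DAN4 (0.68), named after their values were seen, rose. Camera gave an adjusted p of 0.00632 for this list, and the adjusted p was 0.485 with an estimated correlation. It shares 1 gene, HEM13, with the heme biosynthesis list.

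Genes that build the ribosome had the lowest median of the lists, -1.39. Of 64 ribosome assembly factors and RNA polymerase I subunits 56 fell, 8 did not pass and 0 rose (56 lower and 1 higher adjusted over the list alone). The assembly factor genes BFR2 (-2.89 ± 0.16), NOP14 (-2.76 ± 0.12), NOP56 (-2.70 ± 0.12) and UTP14 (-2.65 ± 0.16) fell most. The list had the lowest camera adjusted p of the 41, 5.84e-15, and an adjusted p of 0.485 with an estimated correlation. Most of its members are dim: with the dimmest 40% of genes left out 9 remained, of which 8 fell and 1 rose (median -1.41, camera adjusted p = 0.00301). Of 122 cytosolic ribosomal protein genes, 26 of them on shared probe sets, 93 fell, 2 rose and 27 did not pass (96 lower and 2 higher adjusted over the list alone), with a median of -0.55. The largest decreases were in RPL13A (-1.51 ± 0.12), RPL27B (-1.42 ± 0.11), RPS0B (-1.38 ± 0.15) and RPL9B (-1.20 ± 0.13); RPS14B (0.69) and RPS22B (1.13), named after their values were seen, rose. The camera adjusted p was 5.25e-10, and the adjusted p was 0.6 with an estimated correlation. With the 3' to 5' index as a covariate the median was -1.03, and without CQ replicate 2 it was -0.67. Mitochondrial ribosomal protein genes fell by less, 24 of 43 lower, 2 higher and 17 not past the threshold (23 and 1 adjusted over the list alone), with a median of -0.29. Their largest decreases were in MRPL32 (-0.91 ± 0.13), MRPL15 (-0.87 ± 0.15), MRPL25 (-0.71 ± 0.12) and MRPS8 (-0.69 ± 0.08), and MRPL44 (0.31) and MRPL3 (0.35), named after their values were seen, rose. This list's camera adjusted p was 0.00299, its adjusted p 0.616 with an estimated correlation, and its median -0.48 with the index as a covariate and -0.15 with the coding-length trend removed.

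Drug-resistance genes rose: of 13 targets of Pdr1 and Pdr3, 11 rose, 1 fell and 1 did not pass, the same adjusted over the list alone, with a median of 1.04 (0.62 with the coding-length trend removed). RTA1 rose by 3.30 ± 0.16, the sphingoid base transporter gene RSB1 by 1.93 ± 0.08, and the ABC transporter genes PDR10 and YOR1 by 1.73 ± 0.11 and 1.57 ± 0.09. At -0.28, PDR18, named after its value was seen, fell. With an intensity trend in eBayes 0 members of this list fell. Camera gave an adjusted p of 0.00114, and 0.485 was the adjusted p with an estimated correlation. Cell wall integrity targets were higher in 10 of 13 cases, with 3 not past the threshold and the same adjusted over the list alone (median 0.61, camera adjusted p = 0.00474, adjusted p = 0.35 with an estimated correlation). The chitin synthase gene CHS1 rose by 1.49 ± 0.08, the glucan synthase gene GSC2 by 1.47 ± 0.08, the MAP kinase gene SLT2 by 1.31 ± 0.07 and PIR1 by 0.71 ± 0.08; GSC2 stood at 0.79 with the coding-length trend removed. Of 12 endoplasmic reticulum folding genes 8 rose and 4 did not pass (9 higher adjusted over the list alone), with a median of 0.68. The chaperone genes LHS1, JEM1 and SCJ1 rose by 2.17 ± 0.10, 1.72 ± 0.09 and 1.34 ± 0.12 and the thiol oxidase gene ERO1 by 1.61 ± 0.23 (camera adjusted p = 0.00522, and adjusted p = 0.485 with an estimated correlation).

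Sulfur genes rose and amino acid genes mostly fell. Of 21 sulfate assimilation and methionine genes 17 rose, 2 fell and 2 did not pass, the same adjusted over the list alone, with a median of 0.86. The transcription factor gene MET32 rose by 3.42 ± 0.23, STR3 by 2.54 ± 0.21, MET2 by 1.61 ± 0.12 and the sulfate permease gene SUL2 by 1.60 ± 0.13. MET6 (-0.39) and CYS4 (-0.18), named after their values were seen, fell, and with quantile normalization only 1 member fell. The call (camera adjusted p = 0.00582, and adjusted p = 0.6 with an estimated correlation) was lost with the 3' to 5' index, 0.40 higher with CQ, as a covariate (median 0.30, adjusted p = 0.31) and with the dimmest 40% of genes left out (adjusted p = 0.0777). Of 25 amino acid genes under Gcn4, 14 fell, 4 rose and 7 did not pass, the same adjusted over the list alone, with a median of -0.43. LYS9 (-1.44 ± 0.10), ILV2 (-1.41 ± 0.11) and ARO4 (-1.20 ± 0.14) fell, and ARG3 rose by 1.98 ± 0.18, or 1.26 with the index as a covariate. CPA1, HIS1 and LYS20, named after their values were seen, rose by 0.59, 0.49 and 0.60. The camera adjusted p was 0.00632, and the adjusted p was 0.485 with an estimated correlation.

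Cell cycle and cell identity genes moved in several lists. Of 8 measured G2 and mitosis genes 5 fell, 1 rose and 2 did not pass, the same adjusted over the list alone, with a median of -0.81: the B-type cyclin gene CLB2 (-1.61 ± 0.10), SWI5 (-1.37 ± 0.12), CDC20 (-1.01 ± 0.12, or -0.63 with the index as a covariate) and BUD4 (-0.88 ± 0.07, or -1.42 with the length trend removed) fell, and HST3, named after its value was seen, rose by 0.35. This call was the least firm, at a camera adjusted p of 0.0438 and an adjusted p of 0.537 with an estimated correlation. It was lost without CQ replicate 2 (adjusted p = 0.0678), with arrays centred on their median (adjusted p = 0.0517) and with the 3' to 5' index, 0.40 higher with CQ, as a covariate (adjusted p = 0.223). With the median centring the list's median log2 difference was -0.945, so that loss did not come with a smaller change. Core histone genes were lower in 5 of 7 cases and did not pass in 2, the same adjusted over the list alone, with a median of -0.45 (-0.70 with the index as a covariate). HTB2 (-1.35 ± 0.16), HTB1 (-0.86 ± 0.08), HHT1 (-0.58 ± 0.10) and HHF1 (-0.45 ± 0.09, on a shared probe set) fell most (camera adjusted p = 0.0176, and adjusted p = 0.485 with an estimated correlation). All 4 alpha-specific genes, which mark the mating type of the strain, fell in the count over all genes and adjusted over the list alone. SAG1 went from 6995 ± 277 to 2868 ± 129 (-1.28 ± 0.08), MF(ALPHA)1 from 6685 ± 215 to 2881 ± 234 (-1.21 ± 0.08), and STE3 (-0.75 ± 0.09) and MF(ALPHA)2 (-0.63 ± 0.18) fell by less. The list median was -0.98, with a camera adjusted p of 0.0149 and an adjusted p of 0.35 with an estimated correlation; MF(ALPHA)2 stood at -0.40 without CQ replicate 3 and at -1.34 with the index as a covariate.

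Markers of other cell states were also measured. Of 11 meiosis and sporulation genes 9 rose and 2 did not pass, the same adjusted over the list alone, with a median of 0.69. The regulator genes IME2, NDT80 and IME1 went from 184 ± 13.3 to 970 ± 147 (2.29 ± 0.12), from 172 ± 16.7 to 713 ± 104 (1.95 ± 0.12) and from 268 ± 57.2 to 849 ± 175 (1.61 ± 0.18), and the recombination gene SPO11 from 59.6 ± 5.72 to 166 ± 27.1 (1.26 ± 0.12). Their camera adjusted p was 0.00632, and the adjusted p was 0.485 with an estimated correlation. Stationary phase markers were higher in 8 of 9 cases, with 1 not past the threshold and the same adjusted over the list alone (median 0.76, camera adjusted p = 0.0149, adjusted p = 0.35 with an estimated correlation). SNZ1 rose by 1.34 ± 0.13, HBT1 by 1.26 ± 0.16, SNZ3, on a shared probe set, by 0.92 ± 0.16 and SPG5 by 0.79 ± 0.07. The opposite mating type's a-specific genes were higher in 4 of 6 cases, with 2 not past the threshold and no call (camera adjusted p = 0.145), at low intensities: MFA1 went from 72.6 ± 5.65 to 207 ± 52.0 and MFA2 from 74.4 ± 6.76 to 144 ± 27.8.

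The other lists were not called by camera. Hexose transporters came close (7 of 11 higher, 1 lower, 3 not past the threshold, median 0.62, adjusted p = 0.0505), with HXT5 at 2.95 ± 0.11 and HXT10 at 2.90 ± 0.10; camera called this list in 9 other settings, at adjusted p from 0.0239 (quantile normalization) to 0.0492 (coding-length trend removed), and fry gave an adjusted p of 0.000474. Heat shock chaperones were higher in 13 of 23 cases, lower in 3 and not past the threshold in 7 (median 0.25, adjusted p = 0.0537), with AHA1 at 1.44 ± 0.08 and BTN2 at 2.18 ± 0.72. BTN2 read 3308 on DMSO replicate 1 against 298 and 727 on the other DMSO arrays, and its difference was 1.40 and not past the threshold without DMSO replicate 2. Without DMSO replicate 1 the list was called (adjusted p = 0.0102). The list was also called with quantile normalization (adjusted p = 0.0116), the replicate block (0.0398), a pseudocount of 64 (0.0498) and without CQ replicate 3 (0.0438). Its count of higher members was 5 without DMSO replicate 2, 6 without DMSO replicate 3 or CQ replicate 1, 7 with arrays centred on their median and 3 with the index as a covariate. Phospholipid genes were higher in 5 of 9 cases and not past the threshold in 4 (adjusted p = 0.0734), with INO1, inositol phosphate synthase, at 3.99 ± 0.15 and EKI1 at 0.71 ± 0.12; this list was called with quantile normalization (adjusted p = 0.0387), with the length trend removed (0.0350) and with the index as a covariate (0.0212).

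The proteasome list had 3 higher, 10 lower and 19 not past the threshold (2 higher and 6 lower adjusted over the list alone, adjusted p = 0.145), with RPT5 at -0.50 ± 0.07 and PUP3 at 0.39 ± 0.10. With arrays centred on their median it was called (adjusted p = 0.036) with 19 lower; 6 were lower without DMSO replicate 1, 4 with the length trend removed and 3 with the index as a covariate. Genes of DNA damage or low nucleotides had 1 higher and 6 lower of 9 (adjusted p = 0.246), with the ribonucleotide reductase genes RNR2 at -0.95 ± 0.10 and RNR4 at -0.93 ± 0.08. Late G1 and S phase genes had 3 higher and 7 lower of 13 (adjusted p = 0.283), with RNR1 at -1.20 ± 0.17 and SWE1 at 0.87 ± 0.08, and genes of the end of mitosis and early G1 had 2 higher and 5 lower of 9 (adjusted p = 0.256), with DSE2 at -1.35 ± 0.11 and CTS1 at -0.74 ± 0.09. The glyoxylate cycle and gluconeogenesis list had 3 higher and 5 lower of 11 (adjusted p = 0.316), with SFC1 at 1.49 ± 0.11 and ICL1 at -1.14 ± 0.14, and glycolysis had 2 higher, 3 lower and 11 of 16 not past the threshold (adjusted p = 0.519), with HXK2 at -1.13 ± 0.11 and PFK1 at -0.43 ± 0.07.

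General stress genes had 10 higher, 3 lower and 13 of 26 not past the threshold (8 higher and 3 lower adjusted over the list alone, adjusted p = 0.458), with CTT1 at -2.16 ± 0.11 and GND2 at 1.19 ± 0.14. In this list 6 were higher without DMSO replicate 2 or 3, 4 with the index as a covariate, and with arrays centred on their median 4 were higher and 7 lower. Oxidative stress genes had 9 higher, 5 lower and 8 not past the threshold of 22 (adjusted p = 0.8), with the vacuolar glutathione conjugate transporter gene YCF1 at 1.71 ± 0.10; that centring gave 5 higher and 9 lower. Thiamine genes had 5 higher and 3 lower of 10 (adjusted p = 0.659), with THI4 at 3.91 ± 0.17 and PHO3 at -2.62 ± 0.12, and the phosphate regulon had 6 higher and 3 lower of 14 (adjusted p = 0.667), with PHO89 at 1.85 ± 0.23 and GIT1 at 1.26 ± 0.17. Of 6 genes often used as stable references 3 fell and 3 did not pass (adjusted p = 0.329), with UBC6 at -0.59 ± 0.10 and TUB1 at -0.48 ± 0.08. In these lists without a call the counts adjusted over the list alone equalled those over all genes, except where both are given.

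Among the other counts and values that moved by more than 1.5 times or changed sides were the following. With arrays centred on their median 5 genes of the zinc list fell, the tricarboxylic acid cycle list had 3 higher and 7 lower, glycolysis 1 and 6, the phosphate regulon 6 and 6 and Fe-S cluster assembly 7 and 9. The tricarboxylic acid cycle list had 3 higher and 5 lower without DMSO replicate 2 or 3, and oxidative stress 6 and 6 without CQ replicate 1 and 4 and 4 with the index as a covariate. With the length trend removed 6 general stress genes fell, and 5 mitochondrial ribosomal protein genes and 4 glycolysis genes rose. With the index as a covariate 7 sulfur genes and 5 stationary phase genes rose, and 8 ergosterol genes, 4 late G1 and S phase genes, 2 early G1 genes and 0 reference genes fell. In that fit the log2 difference of HIS3 was -1.43, and HEM4 (-0.97), HHT1 (-0.93), HHF1 (-0.70), MRPL15 (-1.46), MRPL25 (-1.14), MRPL32 (-1.40) and EKI1 (1.09) also moved away from 0. RIP1 (-0.83), STE3 (-0.48), ICL1 (-0.58) and MFA2 (0.40) moved towards it, and MFA2, PUP3, TUB1 and UBC6 did not pass. With the length trend removed PFK1 stood at -0.73 and YOR1 at 1.02, and with arrays centred on their median PUP3 stood at 0.25.

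Among single genes, the largest increases outside the lists were in VBA3 (YCL069W), a transporter family member on a shared probe set, at 5.19 ± 0.08 (limma adjusted p = 3.54e-08), MCH2 (YKL221W), a monocarboxylate permease family member, at 4.98 ± 0.19 (adjusted p = 1.02e-06), and GTO3 (YMR251W), a glutathione transferase, at 3.55 ± 0.27 (adjusted p = 1.6e-05). The largest decrease was in IZH4 (YOL101C), a membrane protein related to IZH1 and IZH2, which went from 2642 ± 130 to 203 ± 29.7 (-3.61 ± 0.11, limma adjusted p = 5.28e-07). The ribosome assembly genes NSA2 (-3.04 ± 0.11) and NOC2 (-2.90 ± 0.13), the cytochrome b5 gene CYB5 (-2.90 ± 0.16), the transcription factor genes SUT1 (-2.87 ± 0.12) and CIN5 (-2.83 ± 0.17), and TDA4 (-2.81 ± 0.11) and YBL081W (-2.81 ± 0.15) followed.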

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

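The tests of the 3' to 5' index in this part were chosen after the index had been seen, as were the tests of length and of scaling for ribosome biogenesis; its test against the index was written before the result.

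The yeast 3' to 5' index, read from control probe sets that the comparison of genes does not use, was higher with CQ than with DMSO by 0.396 on the log2 scale. Labelling or hybridisation of CQ replicates 1 and 3 is argued against, as the source of their share, by the mean of the spike-in RNAs. That mean rose by 0.042 there, within the spread of 0.0465 among DMSO arrays, while the yeast index rose by 0.296. The spike-in RNAs did not move alike, so their mean does not exclude it. For lys the value was 0.31 on CQ replicate 1 and 0.76 on CQ replicate 3, against 0.41 to 0.49 with DMSO. On CQ replicate 2 the spike-in index rose by 0.471 and the yeast index by 0.597, so labelling or hybridisation may account for most of the rise on that array. RNA degradation before or during extraction of the CQ cultures stays open for the other 2 arrays, since the rise of 0.296 would look the same if CQ had altered RNA in living cells, and the design cannot separate these causes.

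The decrease of ribosome biogenesis genes, with a median of -1.39, was weighed against the same signs. Loss of signal that grows with transcript length is argued against by the other genes, of which the longest 25% had a median higher than the shortest 25% by 0.456 (bootstrap 95% 0.402 to 0.507). The bootstrap resampled genes, which are not independent replicates, so the interval holds no variation between arrays. A 3' to 5' bias is argued against by a median of -1.36 with the index as a covariate, though the index separates the groups and the covariate rests on the spread within them. Scaling, which moves every probe set of an array alike, is argued against by the 12 spike-in probe sets, whose median shift was 0.067 (range -0.08 to 0.23). The hybridisation controls bioB, bioC, bioD and cre, at 0.20 to 0.75, were not lower with CQ either. The cause of their larger shift was not tested, and bioB overlapped between the groups and was brightest on CQ replicate 2. Ribosome biogenesis falls in slow-growing yeast, and a change in growth with CQ is a hypothesis these arrays did not test.

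Of 3517 probe sets without a gene name, 431 lay above background, and 26 of these were at least 2-fold higher with CQ and 14 at least 2-fold lower, by limma over these probe sets. Among these, 1 probe set went from 1549 to 7773 (2.31 ± 0.10). Among the 1746 fission yeast probe sets 118 lay above background, with 0 at least 2-fold higher and 2 at least 2-fold lower. The background level was taken from these same probe sets, so the count of 118 is largely set by that definition. The control probe sets of the 18S rRNA were all lower with CQ, from -0.398 to -1.06 (probe set d) on the log2 scale. Those of the 25S rRNA went both ways, from -0.428 (probe set b) to 0.739 (probe set c).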

How the results depend on the processing

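The 3' to 5' index as a covariate and the removal of the coding-length trend were chosen after seeing the data; all other settings were planned. The counts of genes higher with CQ, genes lower with CQ, genes at least 2-fold higher with CQ and genes at least 2-fold lower with CQ stayed within 1.5 times of 1969, 1739, 529 and 409 under every setting except the filter that leaves out the dimmest 40% of genes. That filter gave 1184, 1083, 267 and 177, with fewer genes tested by construction. It also left fewer than 3 members, the fewest tested, in the lists of G2 and mitosis, meiosis, late G1 and S phase and a-specific genes. Leaving out each array in turn gave 1701 to 2109 genes higher, 1526 to 1847 lower, 516 to 565 at least 2-fold higher, 403 to 429 at least 2-fold lower and 21 to 22 lists called. Camera called 0 lists with an estimated correlation and fry, which asks another question, 32, against 21. The estimates lay far above the preset 0.01 for cytosolic ribosomal proteins (0.841), ribosome biogenesis (0.41) and the iron regulon (0.206). They were below 0 for heme biosynthesis (-0.0709), alpha-specific genes (-0.117) and stationary phase markers (-0.087), whose calls were lost too. The size of the correlation alone therefore does not explain the loss. For these 3 lists the camera p before adjustment was 0.0337, 0.0512 and 0.0484 with the estimate. That test also takes its p from only 4 residual degrees of freedom, so a lost call does not by itself show an effect of correlation. The share of each in the loss was not tested. With the index as a covariate the counts were 1596, 1408, 665 and 523, and 20 lists; with the length trend removed they were 1969, 1727, 462 and 390, and 23 lists.

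Directions were kept by the named genes with 4 exceptions, none past the threshold in the reversed fit: URA3 at -0.044 with arrays centred on their median, and CRS5 at -0.092, LEU2 at 0.069 and LYS2 at 0.081 with the index as a covariate. LEU2, LYS2 and URA3 lie near or below background, where signal limits any direction; the cause was not tested. With the length trend removed LYS2 (-0.62) and URA3 (0.23) passed the threshold, and with arrays centred on their median LEU2 (-0.44) did, although the strain lacks these genes. Over all settings named genes gave 2709 fits on the same side of the threshold, 13 that lost it and 4 that gained it; lists gave 883, 27 and 29. Genes dropped by a filter have no value there. With the replicate block there were 1971 genes higher with CQ and 1738 genes lower with CQ, 529 genes at least 2-fold higher with CQ and 410 genes at least 2-fold lower with CQ, and 22 lists were called. The numbers were not treated as pairing in the main fit, a choice made before the data were examined. Deviations of same-numbered arrays correlated at 0.06, 0.12 and 0.14, and every array correlated best with its own number.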

Other observations

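The tests of divergent neighbours were chosen after a neighbour had been seen; the test of downstream neighbours and the splits were planned before their results.

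Genes beside the metal genes were followed up because RKM5, a ribosomal methyltransferase gene that shares its upstream region with TIS11, rose by 2.70. Outside the iron, zinc and copper lists, 47 other measured genes lie next to the 32 genes of these lists that rose at least 2-fold. Of 10 divergent neighbours besides RKM5, 8 rose and 1 fell, among them HER1 beside ISU2 (1.34), CRR1 beside FRE1 (1.29) and LST4 beside ZRT3 (0.89), which were named after their values were seen. Convergent neighbours had a mean of 0.417, with MCH2 beside FRE2 at 4.98, and of -0.153 without MCH2; same-strand upstream ones had a mean of 0.324, with 7 of 12 higher.

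A shared upstream region may account for the divergent neighbours, since their mean was 0.562 against -0.445 to 0.521 for 95% of 100000 random draws, but the permutation p of 0.0337 became an adjusted p of 0.135 over 4 relations, so the hypothesis stays open; with RKM5, which prompted it, the mean was 0.757. Shared chromosome ends are argued against, as the source of that mean, by a mean of 0.872 for the 6 divergent neighbours over 30 kb from an end. Random draws gave -0.59 to 0.67 (permutation p = 0.0116, not adjusted). The draws were not matched for distance to an end, and the rise of the divergent neighbours itself stays open. Read-through into the next gene cannot lead to divergent neighbours. For the 17 same-strand downstream ones, the planned rule counted against read-through if their mean lay within the central 95% of random draws. The mean was 0.0181, within -0.332 to 0.407 (permutation p = 0.925), which argues against read-through as a general source. Of these neighbours 5 rose, GRE2 beside FRE7 by 1.92 and UBP5 beside FTR1 by 1.90, and 7 fell. A mean over genes that go both ways cannot exclude read-through at single genes, which stays open.

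Longer genes were higher with CQ. Across the 5449 genes, which are not independent replicates, coding length and log2 difference had a Spearman rho of 0.221. The medians of 4 equal groups of genes by coding length were -0.09, -0.10, 0.01 and 0.36, and ribosome biogenesis genes were lower in each, at -1.02, -1.52, -1.38 and -1.40.

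The 6 arrays allow 10 splits into 3 and 3, too few for a share under 0.05, and each count was reached by 1 of the 10, the real one. The real split gave 1969 genes higher, 1739 lower, 529 and 409 at least 2-fold, while the others gave 0 after limma's adjustment and 3 to 55 at an unadjusted p under 0.05. For lists the real split gave 21 and the highest of the others 14, and camera at the preset correlation called at least 10 in each. Every other split sets 2 CQ arrays against 1, so it keeps part of the CQ difference, and these calls cannot be read as false.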
